A study of Mus musculus with 20 samples.

How the data were processed

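C/EBPβ ChIP and input DNA were sequenced from 5 conditions of 3T3-L1 cells, with 2 libraries per group and 20 in all. The submitters' processing notes name Bowtie, bedtools and the mouse build mm10, without versions. The names of the peaks begin with MACS, per the deposited files. The caller's version, its threshold, its use of the input libraries and the way replicates were combined are not given in the sources used here.

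Each of the 5 deposited lists gives the chromosome, start, end, name and score of every peak of a condition. The score is the authors' own value per peak, deposited without a header that names its scale. The lowest score is 50 or just above it in every list. Scores were used only to rank or select peaks within a list. A list has no replicate number, so the spread between replicates, and any test that needs it, was out of reach. The depth is unknown. A longer list can come from more reads, better enrichment or more bound sites, and peak lists alone do not separate these.

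Peaks of all lists were merged into sites where they overlapped by at least 1 bp. A site counts as present in a list if a peak of that list lies in it. Shares of sites carry Wilson intervals and ratios of sites found in 1 list only carry exact binomial intervals, both at 95%. Neighbouring sites are not independent, so these intervals are likely too narrow. The reference table (GRCm38.p6, the coordinates of mm10) gave spans of 21887 protein-coding genes, and all 295 list genes were matched. Coordinates are 1-based.

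The plan fixed before the data were examined measured distances from transcription start sites. The table holds no strand, so a site was assigned to every gene whose span lay within 50 kb of its midpoint, and positions within 1 kb of either gene end replaced promoters. Exon, intron and UTR classes and the 19 planned sequence motifs were not analysed here, since no genome sequence was used. Genes with long spans collect more sites, and overlapping or neighbouring genes share them.

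There were 14 gene lists fixed beforehand, 10 of this biology and 4 of other cell types. Their mean number of sites per gene was placed among 10000 random lists of the same size matched on gene density. The change between conditions was placed among random lists matched on the number of merged sites per gene. Percentiles describe these lists and are not p-values; those at or below 2.5 or at or above 97.5 are called outside the limits. In 20 simulations with 40% of a list's sites made specific to a condition, run on 21887 genes for lists of 25, all 20 planted lists reached 97.5 and 0 of the unplanted lists fell outside the limits. There each site fell in either condition at random and independently, and genes with few sites were not drawn. The real peak lists differ in length and share many sites, so power and error rate for these data were not measured.

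Genes were named by a rule fixed beforehand. It took a panel of 12 genes (Cebpa, Cebpb, Cebpd, Pparg, Fabp4, Adipoq, Lpl, Klf5, Srebf1, Parp1, Nampt and Il6) and the list members with the greatest surplus and deficit of sites, up to 10 each. It also took the 5 highest-scoring sites found in 1 list only per direction, and the 5 genes with the greatest surplus and deficit genome-wide. Genes named from the comparisons without and with Dox, and the immediate early genes of the closing section, were chosen after their values were seen.

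Alternatives covered the overlap rule, widened peaks, score and length filters, lists of equal length, covered bp, other windows and nearest-gene assignment. Lists of equal length keep the highest-scoring peaks. They largely remove a general surplus of the longer list by design and leave out its weaker peaks. Differences at equal length therefore do not check the direction of such a surplus. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.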

Results

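C/EBPβ binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in 3T3-L1 cells, a mouse preadipocyte line that can be differentiated into fat cells. C/EBPβ is a bZIP transcription factor that acts early in adipogenesis. The cells carried a doxycycline-inducible, HA-tagged LAP isoform of C/EBPβ, either wild type (WT) or with its poly(ADP-ribosyl)ation sites mutated (Mut). Contact-inhibited cells received vehicle or 1 µg/ml doxycycline (Dox) for 8 h, and 1 set of WT cells also received the PARP inhibitor BYK204165 (BYK) 1 h before Dox. The 20 libraries form 10 groups of 2, a ChIP and an input group for each of 5 conditions. The data used here are 5 peak lists, 1 per condition, without replicate numbers. No difference between conditions therefore has a replicate check, and no p-value is given for any of them. The sequencing depth behind each list is unknown, and all intervals are 95% intervals that cover counting error only.

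Induced mutant cells and induced cells given the inhibitor had the longest lists. The lists held 10959 peaks in WT −Dox, 6898 in Mut −Dox, 12384 in WT +Dox, 17816 in Mut +Dox and 18371 in WT +Dox +BYK. The peaks covered 8.54, 6.29, 11.0, 18.2 and 16.4 Mb, in the same order. Merging overlapping peaks of all lists gave 23854 sites, of which 5209 (21.8%) had a peak in all 5 lists and 7325 (30.7%) in 1 list. Pparg, the nuclear receptor that drives fat cell differentiation, was among the densely bound genes in every condition. Its span on mm10 chromosome 6 (115360879 to 115490404) had 11 sites within 50 kb in WT −Dox, 9 in Mut −Dox, 15 in WT +Dox, 19 in Mut +Dox and 17 in WT +Dox +BYK. The site at 115452103 to 115453466, inside the gene, carried a peak in all 5 lists.

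**Figure D1:**
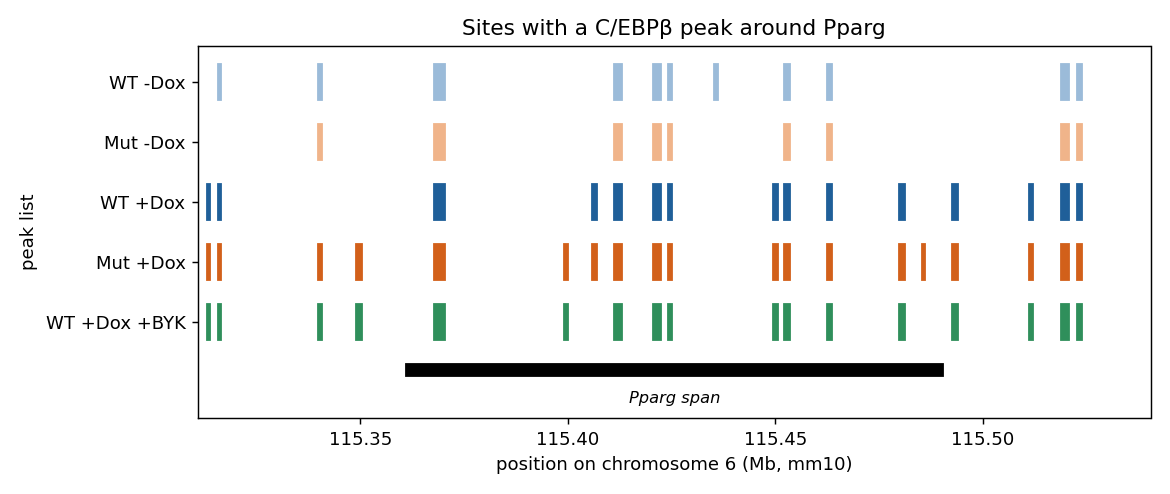
Sites with a C/EBPβ peak around Pparg, with the position on chromosome 6 in Mb on the x axis and the 5 peak lists on the y axis; each block is a merged site drawn where that list has a peak, and the black bar is the gene span. The number of sites goes from 9 in Mut −Dox to 19 in Mut +Dox.

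The comparison of WT cells without and with Dox asks how C/EBPβ sites changed on induction. The ChIP was for C/EBPβ, and the lists without Dox already held many peaks. A peak of a +Dox list therefore cannot be assigned to the induced protein. Genes of the AP-1 and other bZIP list had 31 sites before and 43 after induction, with more sites at 10 genes and fewer at 2. Preadipocyte factors and inhibitors of adipogenesis had 39 sites before and 56 after. These changes lay at percentiles 97.9 and 97.8 of random gene lists with matched numbers of sites. Junb, an AP-1 subunit, had 1 site before and 5 after, and Pparg 11 and 15. Adipoq, which encodes the hormone adiponectin, had 3 and 1. Its WT −Dox sites absent from WT +Dox scored 55.3 and 72.05, where the lowest score was 50.02. Of the 10862 sites of WT −Dox, 8090 (74.5%, Wilson interval 73.7 to 75.3) were in the WT +Dox list, 2772 were lost and 4193 were in WT +Dox only. The ratio of gained to lost sites was 1.51 (exact interval 1.44 to 1.59).

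The same comparison in mutant cells gave gains near most bound genes. At 8478 protein-coding genes the Mut +Dox list had more sites than Mut −Dox, and at 360 it had fewer. Adipocyte lipid and secreted factor genes went from 20 to 68 sites, with more at 20 genes and fewer at 0. Acute phase and inflammatory genes went from 42 to 102, with more at 18 and fewer at 0. Neither list stood apart from random lists (percentiles 83.2 and 35.1). Of 6866 sites in Mut −Dox, 6310 (91.9%, 91.2 to 92.5) were in Mut +Dox, 556 were lost and 11462 were in Mut +Dox only, a ratio of 20.6 (18.9 to 22.5). The ratio was 76.1 when only sites in the upper part of their own list by score, above its median, were counted. That cut takes more sites from the longer list. The gained sites had a median score rank at percentile 35.8 of Mut +Dox. Of them 32.5% lay above its median, against 8.81% of the lost sites in Mut −Dox. Of the 11462 gains, 8623 (75.2%, 74.4 to 76.0) lay at sites with a peak in at least 1 WT list.

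**Figure D2:**
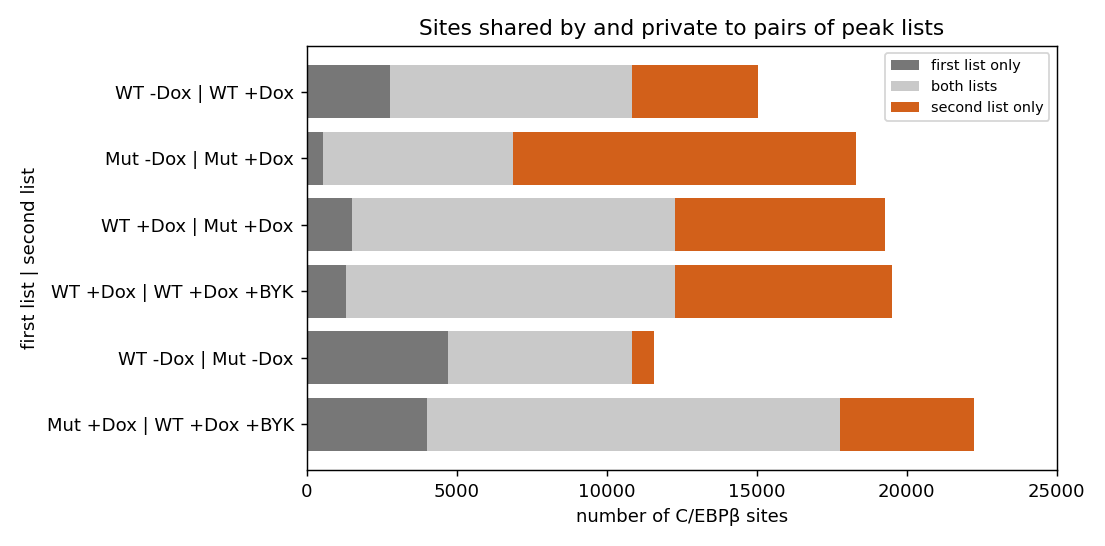
Numbers of C/EBPβ sites (x axis) found in the first list only, in both lists or in the second list only, for pairs of peak lists (y axis). Mut +Dox and WT +Dox +BYK each held about 7000 sites that WT +Dox lacked, while WT +Dox held 1511 and 1302 that they lacked.

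WT +Dox and Mut +Dox were compared to ask whether C/EBPβ sites after induction differ when the induced protein lacks the modified residues. Most genes whose number of sites differed had more in the mutant. Pparg had 15 sites in WT +Dox and 19 in Mut +Dox, Ebf1, a transcription factor of the fat cell lineage, 7 and 14, Ppargc1a, a coactivator of Pparg, 4 and 9, and Adipoq 1 and 4. Fbn1 (chromosome 2, 125300594 to 125506485), which encodes the matrix protein fibrillin 1, had 13 and 21, and Dcn, which encodes decorin, 4 and 10. With 6898 peaks from each list, the difference was 0 for Pparg, Ebf1, Ppargc1a and Adipoq, 3 for Fbn1 and 5 for Dcn. The Mut +Dox sites absent from WT +Dox scored 61.5 to 86.7 near Adipoq and 80.7 to 132 near Pparg. The lowest score of the Mut +Dox list was 50.01 and its median 107. Genes of the AP-1 and other bZIP list went the other way, from 43 sites to 35.

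Among adipogenic transcription factors, 9 of the 18 genes with any site had more sites in Mut +Dox and 2 had fewer, and the list's sites numbered 51 and 74 (percentile 75.8), or 30 and 28 with 6898 peaks from each list. Cebpa had 1 and 2 sites, Cebpb 1 and 0, and Cebpd, Klf5 and Srebf1 had 0 in both. Of the adipocyte lipid and secreted factor genes, 15 had more and 3 fewer. Fabp4, the fatty acid carrier of fat cells, had 1 and 2, Lpl, lipoprotein lipase, had 4 and 5, and Slc2a4, the insulin-regulated glucose transporter, had 3 and 2. The Mut +Dox site absent from WT +Dox scored 58.8 near Cebpa and 51.5 near Fabp4, close to the lowest score of 50.01. Among PARP and NAD genes, 10 had more sites and 3 fewer. Macrod2 had 9 and 17, Tnks, which encodes tankyrase, 1 and 6, Nampt 1 and 2, Parp1 1 in both and Macrod1 1 and 0. With 6898 peaks from each list, the differences were 1 for Macrod2 and 0 for Tnks, and the list had 24 and 21 sites. At that length 2 of the 14 lists had more sites in Mut +Dox, 10 fewer and 2 equal numbers. Tcf7l2, a Wnt pathway factor, had 5 and 12, Csf1, a macrophage growth factor, 7 and 12, and Gadd45a, a stress gene, 5 and 9. Il6 had 4 in both, and 2 fewer in Mut +Dox at equal length.

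In the AP-1 and other bZIP list, 8 of 19 genes with a site had fewer sites in Mut +Dox, 3 had more and 8 had equal numbers. Junb (chromosome 8, 84976909 to 84978748) had 5 in WT +Dox and 2 in Mut +Dox, and Jdp2 (chromosome 12, 85598656 to 85639878) had 4 and 1. The list's change lay at percentile 0 of 10000 random lists. When each list was shortened to its 6898 highest-scoring peaks, the list had 21 and 17 sites and lay at percentile 20.4, within the limits. With all peaks, the other 13 lists were within the limits of 2.5 and 97.5. Among the 6898 highest-scoring peaks, fibroblast and matrix genes were the list outside them, with 52 sites in WT +Dox and 66 in Mut +Dox (percentile 99.6). Acute phase genes fell below the limit for sites within 10 kb (42 in both, percentile 0.695) and with nearest genes (82 and 93, percentile 0.30). With nearest genes, preadipocyte factors (76 and 96, percentile 2.28) and the hepatocyte list of another cell type (3 and 1, percentile 0.66) fell below it too. The acute phase genes Saa3 and Hp, at 3 sites in WT +Dox and 1 in Mut +Dox each, belong to a list that had 83 and 102 sites in all. Other list members with fewer sites were Cdkn1a (3 and 2), Ccn1 (4 and 3), Dlg4 (4 and 3) and Itgam (2 and 1), while Snap25, a neuronal gene, had 2 and 7. At equal length Jdp2, Saa3, Hp, Ccn1, Dlg4 and Itgam did not differ, and Junb had 2 sites fewer in Mut +Dox. With each site given to its nearest gene, Junb and Itgam did not differ and Cdkn1a had 1 site more in Mut +Dox. There the difference was -2 for Jdp2 and -1 for Saa3, Hp, Ccn1 and Dlg4. Within 10 kb it was -2 for Junb, -1 for Jdp2 and 1 for Cdkn1a.

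Across all protein-coding genes, 5427 had more sites in Mut +Dox and 1626 had fewer. The genes with the greatest surplus had long spans: Plcb1 (chromosome 2, 134786164 to 135475258) had 12 sites in WT +Dox and 27 in Mut +Dox, Unc5c 3 and 14, Lrmda 20 and 30, Ankrd44 4 and 14 and Magi1 12 and 21. At equal list length the differences were 2 for Plcb1 and Lrmda, 0 for Unc5c and Ankrd44 and -4 for Magi1. The greatest deficits were at Gm38510 (5 and 0), C130026I21Rik (4 and 0) and Gm7592 (3 and 0), neighbours on chromosome 1 that belong to a family of similar copies, so their peaks are uncertain. C130026I21Rik lies within the span of Gm38510, so its sites are counted for Gm38510 too. Sufu had 7 and 3 and Ilf2 6 and 3. The chromosome 1 neighbours did not differ at equal length, and Sufu and Ilf2 each differed by -1. Of 12283 sites in WT +Dox, 10772 (87.7%, 87.1 to 88.3) were in Mut +Dox, 1511 were not, and 7000 were in Mut +Dox only. The ratio of Mut-only to WT-only sites was 4.63 (4.38 to 4.90), and 11.2 among sites above their own list's median score. That cut takes more sites from the longer list, and the Mut-only sites were mostly low-scoring. Their median score rank was at percentile 25.8 of Mut +Dox. Of them 15.6% lay above its median, against 6.35% of the WT-only sites in WT +Dox.

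The highest-scoring Mut +Dox site absent from WT +Dox lay on chromosome 16 (51966700 to 51967698), 64.0 kb from Cblb, with an authors' score of 414. The next were nearest Nmbr (chromosome 10, 15313223 to 15314599), Nrp1 (chromosome 8, 128200357 to 128202245), Bnc2 (chromosome 4, 84621715 to 84623804, inside the gene) and Slc1a3 (chromosome 15, 8563101 to 8564192). Each of these 5 sites also had a peak in WT −Dox. In the other direction, the highest-scoring sites lay inside Gm46608 (chromosome 17, 10319409 to 10320641, score 229) and Smim10l1 (chromosome 6, 133104742 to 133106207). They were followed by a site 583 kb from Adgra3 and sites inside Syk and Cc2d2a.

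The inhibitor comparison asks the same question within the WT line. Most genes whose number of sites differed had more with the inhibitor. Dcn had 4 sites in WT +Dox and 10 with the inhibitor, Lpl 4 and 9, Adipoq 1 and 5, and Dusp1, a MAP kinase phosphatase induced by glucocorticoids, 1 and 7. The chemokine genes Ccl2 and Ccl7, neighbours that share sites, each had 4 and 9. The AP-1 and other bZIP list had 43 sites in both lists, while the other 13 lists had more with the inhibitor. With 6898 peaks from each list, 5 lists had more, 8 fewer and 1 equal numbers. Lists of equal length leave little room for a general surplus, so that setting cannot check its direction. With 6898 peaks from each list, the difference was 2 for Dcn, 1 for Dusp1, 0 for Adipoq, Ccl2 and Ccl7 and -1 for Lpl.

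In the lists, 12 adipogenic transcription factor genes had more sites with the inhibitor and 1 had fewer, and 16 of the lipid and secreted factor genes had more and 1 fewer. Both lists had fewer at equal length, with 30 sites in WT +Dox and 27 with the inhibitor for the first and 25 and 24 for the other. Pparg had 15 and 17 sites, Ebf1 7 and 12, Cebpa 1 and 2, Cebpb 1 and 2, Srebf1 0 and 1, and Cebpd and Klf5 0 in both. The inhibitor sites absent from WT +Dox scored 54.2 near Cebpa, 71.6 near Cebpb and 53.0 near Srebf1. Near Adipoq they scored 51.1 to 78.7. The lowest score of the inhibitor list was 50.01. Among PARP and NAD genes 16 had more and 0 fewer, with Macrod2 at 9 and 16 and Parp1 at 1 and 2, while Nampt had 1 in both; the list had 24 and 23 sites with 6898 peaks from each list. Fbn1 had 13 and 18, Tcf7l2 5 and 10, Gadd45a 5 and 9 and the neuronal gene Syt1 3 and 7. Fabp4 had 1 and Il6 4 in both lists. Fewer sites were found at Junb (5 and 3), Jun (2 and 0), Fos (1 and 0), Maff (1 and 0), Nr1h3 (4 and 3), Cd36 (2 and 1), Sox9 (2 and 1) and Ccn1 (4 and 3). Id3 (5 and 3) and E2f2 (4 and 2) are neighbours that share sites. Once lists were of equal length, Id3, E2f2, Sox9 and Nr1h3 each had 1 site more with the inhibitor, and Jun, Fos, Maff, Cd36 and Ccn1 did not differ. The AP-1 and other bZIP list lay at percentile 0.035 of random lists, and at 79.4, with 21 and 23 sites, among the 6898 highest-scoring peaks of each list. The other 13 lists were within the limits.

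Genome-wide, 6553 genes had more sites with the inhibitor and 1105 had fewer. Glis3 had 12 sites in WT +Dox and 22 with the inhibitor, Dgki 8 and 18, Rad51b 23 and 32, Tenm4 10 and 19 and Palld 12 and 20. Among the 6898 highest-scoring peaks of each list, the differences were -2 for Glis3, -1 for Tenm4, 0 for Dgki, 2 for Rad51b and 1 for Palld. Deficits were again greatest at Gm38510 (5 and 2), C130026I21Rik (4 and 1) and Gm7592 (3 and 0), followed by Map4k2 (4 and 1) and Sf1 (3 and 0). Of the 12283 WT +Dox sites, 10981 (89.4%, 88.8 to 89.9) were in the inhibitor list, 1302 were not, and 7242 were in the inhibitor list only, a ratio of 5.56 (5.24 to 5.90). It was 12.2 among sites above their own list's median score, a cut that takes more sites from the longer list. The sites found with the inhibitor only had a median score rank at percentile 25.2 of that list. Of them 14.1% lay above its median, against 6.37% of the sites found in WT +Dox only. The highest-scoring inhibitor sites absent from WT +Dox were nearest Cav2 (chromosome 6, 17200626 to 17206387), Lamb1 (chromosome 12, 31218421 to 31220121), Efcab1, Nmbr and Boc. Each of these sites also had a peak in WT −Dox and Mut +Dox. Those of WT +Dox absent from the inhibitor list were nearest Vmn1r2 (chromosome 4, 3079581 to 3086905, a site 88.8 kb from the gene), Izumo4, Cdc42se1, Man2c1 and Tank. Each of them had a peak in every list but that of the inhibitor.

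The gains of the mutant and of the inhibitor over WT +Dox were then set against each other. Pparg, Ebf1, Fbn1, Dcn, Tcf7l2, Macrod2 and Gadd45a had more sites in both when all peaks were used. With 6898 peaks from each list, Fbn1 (3 in the mutant and 4 with the inhibitor), Dcn (5 and 2) and Gadd45a (2 and 2) had more in both, while the differences were 0 and -2 for Pparg, 1 and -2 for Macrod2 and 0 and 1 for Ebf1 and Tcf7l2. Of the 7000 Mut-only sites, 3633 (51.9%, 50.7 to 53.1) were in the inhibitor list, and these were 50.2% (49.0 to 51.3) of the 7242 inhibitor-only sites. Independent gains among the 11571 sites absent from WT +Dox would share 4381, but sites enter that pool only if some list called them. Taken over their own uninduced lists, the gains shared 4826 sites, where independent gains among all 23854 sites would share 4301. That pool includes sites of the uninduced lists, where a shared gain is impossible. In a comparison added after seeing the data, independent gains among the 12273 sites absent from both uninduced lists would share 5588. This pool too holds only sites that some list called, so no excess over chance is claimed for either set of gains. Of the 1511 and 1302 losses from WT +Dox, most of them low-scoring sites, 654 were shared. Losses independent within 20 equal parts of the WT +Dox list by score, a comparison added after seeing the data, would share 345. Both comparisons use the same WT +Dox list, so part of that excess may come from it; chance sharing was not simulated because the lists hold no counts.

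The uninduced lists also differed in length, with 6898 peaks in Mut −Dox and 10959 in WT −Dox. Fewer sites lay near adipocyte lipid and secreted factor genes in Mut −Dox (20) than in WT −Dox (39), with more at 0 genes and fewer at 14. AP-1 and other bZIP genes had 15 and 31 sites, and stress response genes 32 and 50. Adipoq had 0 sites in Mut −Dox and 3 in WT −Dox, Pparg 9 and 11 and Lpl 5 in both. The WT −Dox sites near Adipoq scored 51.9, 55.3 and 72.05, where the lowest score was 50.02. All 14 lists were within the random limits, with stress response genes at percentile 3.21 and AP-1 genes at 3.48. Of 10862 WT −Dox sites, 6147 (56.6%, 55.7 to 57.5) were in Mut −Dox, which had 719 sites of its own, a ratio of Mut-only to WT-only sites of 0.152 (0.141 to 0.165). The ratio was 0.392 in covered bp and 0.0330 among sites above their own list's median score, a cut that takes more sites from the longer list. With 6898 peaks from each list the overlap was 76.1%. Of the top 1717 Mut −Dox sites by score, 100% were in WT −Dox. Of the top 2716 WT −Dox sites, 96.2% were in Mut −Dox. A shorter list cut from similar binding would give this, so a difference between the cells is not shown.

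**Figure D3:**
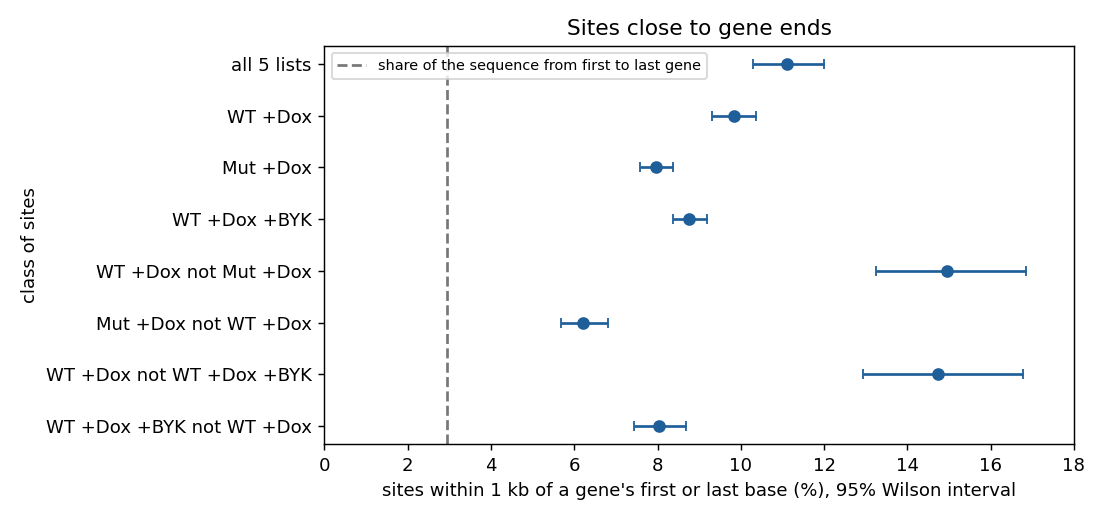
Percent of sites within 1 kb of the first or last base of a protein-coding gene (x axis, with 95% Wilson intervals) for classes of sites (y axis); the dashed line is the share of the sequence between the first and last gene of each chromosome. WT +Dox sites absent from Mut +Dox stand at 15.0% and Mut +Dox sites absent from WT +Dox at 6.21%.

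Sites near gene ends were more frequent among those found in WT +Dox alone than among those it lacked. Of the WT +Dox sites absent from Mut +Dox, 15.0% (13.2 to 16.8) lay within 1 kb of a gene's first or last base, against 6.21% (5.67 to 6.80) of the Mut-only sites. The ratio of these shares was 2.41 (2.07 to 2.80). Against the inhibitor list the shares were 14.7% (12.9 to 16.8) and 8.04% (7.43 to 8.69), a ratio of 1.83 (1.58 to 2.14). The contrast also appeared without the WT +Dox list: 11.5% (9.12 to 14.4) of Mut −Dox sites absent from Mut +Dox lay there, against 6.63% (6.19 to 7.10) in the other direction. It did not appear in the other 2 pairs. Of sites found in 1 list of the pair only, 7.65% (5.92 to 9.83) in Mut −Dox and 9.20% (8.41 to 10.1) in WT −Dox lay there, and 8.69% (7.70 to 9.80) in WT −Dox and 8.32% (7.52 to 9.20) in WT +Dox. Such positions make up 2.94% of the sequence, and 11.1% of the sites in all 5 lists lay there. WT-only sites had on average 2.01 genes within 50 kb (SE 0.0519) and Mut-only sites 1.36 (SE 0.0185). Inside gene spans lay 47.8% (45.3 to 50.4) of the WT-only sites, 48.3% (47.7 to 48.9) of all merged sites and 38.4% of the sequence. Strand was not used here, so start and end of genes are not told apart.

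**Figure D4:**
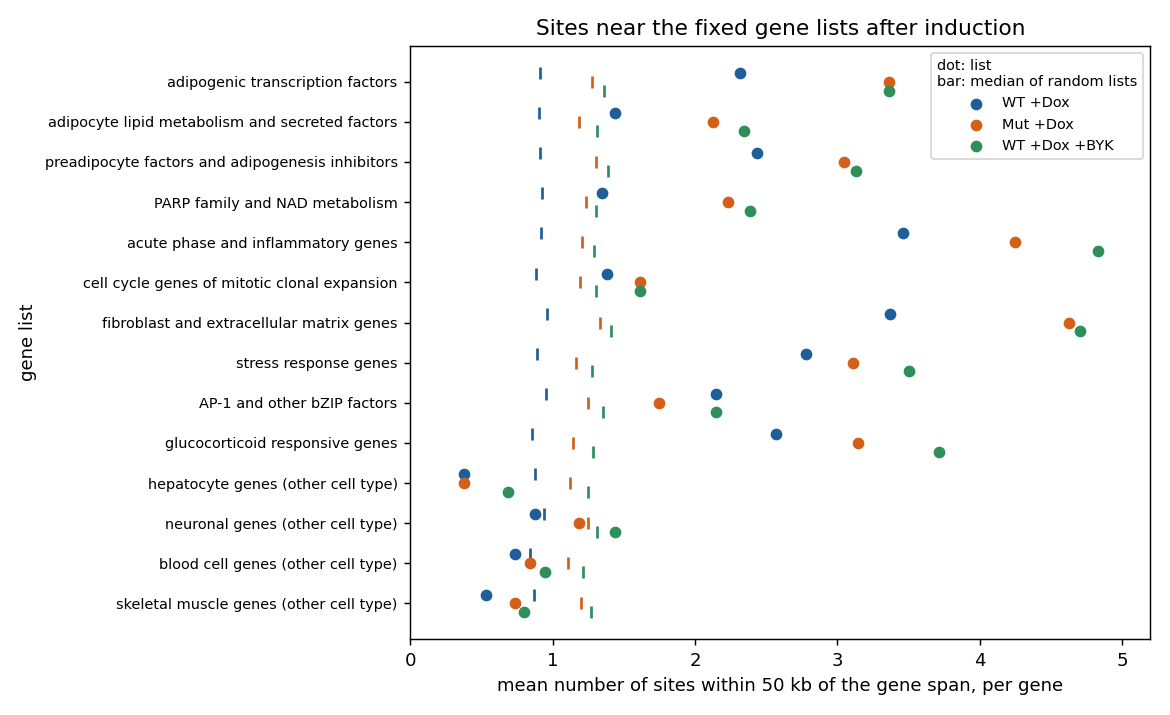
Mean number of sites within 50 kb of the gene span per gene (x axis) for the 14 gene lists (y axis) in WT +Dox, Mut +Dox and WT +Dox +BYK; dots are the lists and vertical bars the medians of 10000 random lists. Acute phase genes stand at 3.46, 4.25 and 4.83 sites, while the lists of other cell types lie near or below their random medians.

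Inflammatory and matrix genes were densely bound in every condition. Acute phase and inflammatory genes had 3.46 sites per gene in WT +Dox against a median of 0.917 in random lists, fibroblast and matrix genes 3.37 against 0.963, and stress response genes 2.78 against 0.889. Glucocorticoid responsive genes had 2.57, preadipocyte factors 2.43 and adipogenic transcription factors 2.32. These 6 lists lay above percentile 99 in all 5 conditions. The lipid and secreted factor list lay at percentile 74.1 in Mut −Dox, 96.5 in WT +Dox, 98.8 in Mut +Dox and 99.3 with the inhibitor. The AP-1 list stood at 99.7 in WT +Dox and 84.2 in Mut +Dox, PARP and NAD genes at 91.2 and 98.2, and cell cycle genes at 93.7 and 85.9. With random lists matched on span length too, a choice made after seeing the data, AP-1 genes stood at 99.99 and 97.8, PARP and NAD genes at 79.6 and 95.1 and cell cycle genes at 98.9 and 97.3. Of the lists of other cell types, hepatocyte genes lay at percentile 3.98 in WT +Dox and 1.08 in Mut +Dox, neuronal genes at 44.9 and 45.7, blood cell genes at 31.7 and 23.0 and muscle genes at 12.8 and 14.0. Over all 5 pairs of lists, 70 changes were computed, of which 4 lay outside the limits, where chance gives 3.5. These were the AP-1 list at percentiles 97.9, 0 and 0.035 and preadipocyte factors at 97.8, all in pairs with WT +Dox. The AP-1 changes share its count of 43 sites in WT +Dox. The 70 changes are not independent, so the count does not tell whether these changes are chance.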

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

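The tests of explanations for the longer lists were chosen after the results were seen. Sites that went in opposite directions on induction in the 2 lines drew attention: 981 sites were lost in WT cells and gained in mutant cells, and 43 were gained in WT cells and lost in mutant cells. The difference was not tested, since each condition has 1 list. Of the 981 sites, 665 (67.8%, 64.8 to 70.6) also had a peak in WT +Dox +BYK. Their median score rank was at percentile 33.0 of the Mut +Dox list and 23.5 of the WT −Dox list, so they are mostly weaker sites. By comparison, 2815 sites were gained and 203 lost in both lines.

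The pattern behind them is that the Mut +Dox and inhibitor lists are longer than WT +Dox. Wider peaks are not the whole of it, since Mut-only sites were still 4.64 times the WT-only sites with peaks widened by 500 bp. Of the Mut-only sites, 10.8% were in Mut −Dox, the shortest list with 6898 peaks. With all Mut +Dox sites cut into 4 equal parts by score, 8.44% of the lowest part and 17.5% of the next were there. Weak sites are thus seldom in that list, so the share cannot tell whether the Mut-only sites were bound before induction. The lowest score was 50.03 in WT +Dox and 50.01 in Mut +Dox and with the inhibitor. This argues against a different score cut-off, though other calling settings are unknown. A difference in depth or enrichment stays open: 98.4% of the top 4443 Mut +Dox sites by score were in WT +Dox, as a shorter list cut from similar binding would give. Wider binding when C/EBPβ is not ADP-ribosylated may produce the same picture, and nothing here tests it.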

How the results depend on the processing

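The ratios among sites above the median score, the gains over uninduced lists, the matching on span length and the sites below the median score were chosen after seeing the data. No paired analysis was possible because the lists carry no replicate number, which also ruled out leaving out a replicate. A stricter common threshold was not run, as scores of different lists are not comparable, nor were motif settings. The ratio is fixed for lists of equal length and was left out there. No ratio of sites found in 1 list only crossed 1. Its side of 1 follows largely from which list is longer, and the settings kept that order, so this is not a check. Peak numbers stayed within 1.5 times, and restricting to autosomes and X, widening peaks or removing peaks over 5 kb kept overlaps and ratios within their intervals. Unknown depth limits every comparison of list length. The cause was not tested for the values that follow.

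The pairs are given in the order WT −Dox with WT +Dox, Mut −Dox with Mut +Dox, WT +Dox with Mut +Dox, WT +Dox with BYK, and WT −Dox with Mut −Dox. With reciprocal overlap of 50%, the first 4 overlaps were 72.8%, 87.9%, 84.7% and 88.0%, and the ratios of pairs 2 to 4 were 14.1, 3.87 and 5.03. In covered bp, the first 4 overlaps were 72.7%, 88.4%, 85.8% and 84.0%, and the 5 ratios 2.07, 17.3, 5.60, 4.06 and 0.392. In the upper part of each list by score, the last 4 overlaps were 93.0%, 89.5%, 91.6% and 58.0%, with ratios of 23.5, 5.24, 6.79 and 0.122. With equal numbers of peaks the 5 overlaps were 70.5%, 66.6%, 77.9%, 79.4% and 76.1%. Among sites above the median score and absent from the other full list, the ratios were 1.94, 76.1, 11.2, 12.2 and 0.0330. The cut at each list's own median takes more sites from the longer list, so these ratios depend on list length.

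The share of Mut gains found with BYK was 56.2% in the upper part by score, 43.2% with equal numbers of peaks, 42.7% in covered bp and 42.1% over uninduced lists. The ratio of shares near gene ends was 1.72 and 1.32 within 5 kb, and 1.98 and 1.57 with all annotated genes, against Mut +Dox and BYK. Gene lists outside the limits numbered 2 within 10 kb and 4 with nearest genes for Mut +Dox, and 0 with equal numbers of peaks for BYK. With equal numbers it was 1 for Mut +Dox, but fibroblast and matrix genes (percentile 99.6) in place of AP-1 genes. There the AP-1 difference from WT +Dox to BYK turned to 0.0645 per merged site. Of 74 nonzero differences of named genes, 72 kept their sign within 100 kb, 63 within 10 kb, 57 with nearest genes and 27 with equal numbers of peaks, where 11 had the opposite sign. Of 26 nonzero differences of gene lists, 7 kept their sign with equal numbers of peaks and 17 had the opposite sign, and 0 did so within 10 kb, within 100 kb or with nearest genes. Equal numbers of peaks largely remove the surplus of the longer list by design, so the signs there do not check its direction.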

Other observations

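Immediate early genes, the first to respond to growth factors, were examined outside the fixed lists, with 30 members chosen after the AP-1 result was seen. They had 41 sites in WT −Dox and 52 in WT +Dox, and 22 and 57 in Mut −Dox and Mut +Dox. Klf6 had 3 sites in WT +Dox and 5 in Mut +Dox, Phlda1 3 and 6, and Csrnp1 1 and 0. In Mut +Dox 7 of the 30 had more sites than in WT +Dox and 7 had fewer.

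The tests of chance peaks, of the cell lines and of scores against the inhibitor list below were chosen after related values were seen. WT +Dox sites that the other induced lists lack lie closer to gene ends. Among sites below their own list's median score, the ratio of shares against Mut +Dox was 2.21 (1.89 to 2.60). Low scores alone do not account for the contrast there, though scores below the median were not matched. Against the inhibitor list the ratio was 1.66 (1.41 to 1.96), which does not meet a stricter bound set beforehand for Mut +Dox. The bound for the inhibitor was lowered after this value was known, so low scores stay open there. A difference between the lines does not give all of the contrast, as the ratio with all sites was 1.83 (1.58 to 2.14) against the inhibitor list of the same line. It was 2.41 (2.07 to 2.80) against Mut +Dox, and both use the same WT +Dox list, so a part from the lines stays open. Of the 226 WT +Dox sites near gene ends that Mut +Dox lacks, 67.3% (60.9 to 73.0) had a peak in WT −Dox or WT +Dox +BYK. Most are thus not chance peaks of the WT +Dox libraries alone. That share was 64.2% (61.7 to 66.6) for all 1511 sites that Mut +Dox lacks, so it does not set gene-end sites apart. Of the WT +Dox sites absent from both other induced lists, 14.8% (12.3 to 17.8) lay near gene ends. Chance peaks as a part of the contrast are therefore not excluded. Mut −Dox sites absent from Mut +Dox show the contrast too (11.5% against 6.63%). The shorter list does not in the pairs of WT −Dox with Mut −Dox (7.65% against 9.20%) and with WT +Dox (8.69% against 8.32%). A biological effect of ADP-ribosylation was not tested.

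The AP-1 and other bZIP list had fewer sites in Mut +Dox than in WT +Dox. Sites near gene ends are a part but not the whole of it. With all sites the list had 43 in WT +Dox and 35 in Mut +Dox. Without sites near gene ends it had 31 and 26 and lay at percentile 0.03. Whether it reflects chance peaks is open: 42.9% of the 14 list sites that Mut +Dox lacks (exact interval 17.7 to 71.1) were in another WT list. It was hypothesised to be a feature of immediate early genes at large, and the 30 other genes lay at percentile 4.46, between the limits set for and against. Among the 6898 highest-scoring peaks of each list the difference per merged site was -0.129, against -0.140 with all peaks, but the list no longer stood apart from random lists (percentile 20.4), whose median moved from 0.180 to -0.0345; a biological cause was not tested.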
